A study of Mus musculus with 10 samples.

How the data were processed

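RNA of 5 sorted fractions of E14Tg2a.4 mouse ES cells was sequenced, with 2 libraries per fraction and 10 in all. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made with the NEBNext Ultra RNA kit, and per the series' design text they were run on a HiSeq2500. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, TopHat2 2.0.14, Cufflinks and Cuffdiff 2.2.1, with the mouse genome build mm10. The gene annotation, the way replicates were merged and the library normalization are not given in the sources used here. Row identifiers are of the UCSC known gene kind.

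The deposited table holds FPKM values made by the authors, 1 per row and fraction, although it is titled as counts: the values are not whole and each column sums to about the same total. Each fraction's 2 libraries are merged into that 1 value. FPKM divides by transcript length and mapped fragments, so depth is lost, and in the 2 pairs of columns examined, double-negative with single-positive and Zscan4-negative with Zscan4-positive, low values showed no common step from which whole reads could be recovered. Multiply mapped reads can lower genes with many processed pseudogenes. Gapdh was listed at 0.845 to 1.24 FPKM, so single values of such genes were not read as levels. Very short RNAs can take extreme FPKM values.

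The table has 32361 rows and 30339 symbols, and 11451 rows were at 0 in every fraction. Rows of 1 symbol were kept apart. Symbols in date form, of which there were 26, were left as deposited. Rows with at least 1 FPKM in at least 1 fraction were compared, 13595 in all, of which 13070 matched a symbol or synonym in a RefSeq gene table and 12915 were protein-coding or long noncoding. Coordinates are those of the deposited table, whose starts count from 0, written from 1. Those of Esrrb and Zscan4c equal the gene coordinates of GENCODE M21 on the same assembly.

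Before the data were examined, a quasi-likelihood test per gene and competitive list tests over all 10 libraries had been chosen. None of these could be run on 1 value per fraction. Each comparison is therefore the difference of log2(FPKM + 1) between 2 fractions, which understates the difference of low genes, with a size rule of 2-fold. A total of 23 gene lists with 355 genes was fixed before the data were examined. For each, the median difference was set against 10000 random lists of the same size drawn from the same 20 expression bins, with the middle 95% as range. This describes these columns and is not a test of the sorted states. Lists for T-lineage genes and interferon response genes, with 13 genes each, were added after values had been seen, as was a set of 4 Y-linked genes.

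Genes were named by a rule fixed before the data were examined, without its test and replicate parts: the 10 largest differences in each direction, 5 for the double-positive comparison, among genes past 2-fold with at least 5 FPKM in the higher fraction, and up to 4 members per list past 2-fold. Some genes this rule picked are not reported here. The first pass picked many short RNAs and unmatched rows: 9 of 10 higher and 6 of 10 lower in the Esrrb step, 8 and 6 of 10 in the Tbx3 step, 5 and 4 of 5 in the double-positive comparison, and 4 and 10 of 10 in the Zscan4 sort. One of them was Mir3968, listed at 1675 FPKM in single-positive cells and at 0 in the other fractions. The rule was therefore applied again to protein-coding and long noncoding symbols, and in the Tbx3 step and the double-positive comparison also without the shared profile. These restrictions and the profile itself were chosen after the values were seen. The profile's minimum in double-negative cells was lowered from 5 to 1 FPKM after a first count, and because it asks for low values in double-positive cells it can only reduce the lower counts there. Genes named outside the rule, such as Mreg, Mest, Hprt, Xist and Y-linked genes, were chosen after their values were seen.

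Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data for the Zscan4 sort, with the 13595 rows and a random spread of 0.2 (log2). Of 40 rows planted at each size, 2.5% of those at 1.5-fold, 50% at 2-fold, 95% at 3-fold and 100% at 4-fold passed the 2-fold rule, and 0.0149% of unchanged rows did. Changes were planted only in rows with a mean of at least 5 FPKM. The spread was set and not measured, since replicate values are lacking, so these shares are not error rates of the real counts. Of 100 unchanged lists of 15 genes, 5% lay outside the random range, and of 100 lists shifted by 0.3, 98% lay above it. The share of unchanged lists follows from how that range is set. Rows were simulated independently, while genes of a real list can vary together, so these shares are not error rates of the real lists. Alternatives covered the pseudocount, the filter on low values, 2 scalings of the columns, summed rows, the kind of symbol and the shared profile.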

Results

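Mouse embryonic stem (ES) cells of the E14Tg2a.4 line were separated by fluorescence-activated sorting and their RNA was sequenced. One reporter line carried knock-in fluorescent reporters of both Esrrb and Tbx3, genes of the naive pluripotency network, and gave 3 fractions: Esrrb-negative/Tbx3-negative (double-negative), Esrrb-positive/Tbx3-negative (single-positive) and Esrrb-positive/Tbx3-positive (double-positive). The other line carried a piggyBac reporter driven by a fragment of the Zscan4c promoter, which marks a rare ES cell state with transcripts of the 2-cell embryo, and gave a Zscan4-positive and a Zscan4-negative fraction. The labels list 2 libraries for each of the 5 fractions, collected on different days. The deposited values hold 1 FPKM value (fragments per kilobase of transcript, scaled to all mapped fragments) per gene and fraction, so no difference below has a replicate check, an SD or a p-value, and read depth is unknown. FPKM totals were 507495 in the double-negative, 522869 in the single-positive, 552117 in the double-positive, 531091 in the Zscan4-negative and 551767 in the Zscan4-positive fraction. Differences are log2 values of FPKM plus 1, and a gene is called higher or lower where it differed at least 2-fold on that scale. Of 32361 annotated rows, 13595 reached 1 FPKM in at least 1 fraction and were compared. The closest fractions were the double-positive and the Zscan4-negative fraction, with r = 0.984 across rows, and the most distant were the double-negative and the Zscan4-positive fraction, with r = 0.883. Double-positive and single-positive cells had r = 0.954. The double-negative and single-positive columns share a profile described with the Tbx3 step, and r was not recomputed without it.

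The sorted genes followed the labels. Esrrb, an orphan nuclear receptor gene on chromosome 12 (mm10, 86361117 to 86521628, plus strand), was at 43.3 FPKM in the double-negative, 177 in the single-positive and 243 in the double-positive fraction. Tbx3, a T-box factor gene on chromosome 5 (mm10, 119670862 to 119684724, plus strand), was at 0.638, 1.75 and 12.6 FPKM in the same order. Zscan4c on chromosome 7 (mm10, 11005745 to 11010547, plus strand) was at 120 FPKM in Zscan4-positive and 0.255 FPKM in Zscan4-negative cells. Its relatives Zscan4a, Zscan4d and Zscan4b reached 151, 123 and 24.3 FPKM in Zscan4-positive cells, and the 2 rows named Zscan4f reached 62.2 and 31.2 FPKM. Zscan4b was listed at 0 in Zscan4-negative cells. These near-identical copies share reads, so the split among them is uncertain. Both other reporters were also read in the Zscan4 line, where Esrrb was at 203 FPKM in negative and 233 in positive cells and Tbx3 at 11.4 and 35.3 FPKM.

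The Esrrb step compared single-positive with double-negative cells, which asks what accompanies Esrrb expression while Tbx3 is low. Naive pluripotency factors were higher with Esrrb: Nanog was at 278 against 79.8 FPKM, Klf4 at 65.5 against 14.5, Zfp42 at 428 against 101 and Tfcp2l1 at 63.0 against 11.8. Of 16 naive factors measured, 12 were at least 2-fold higher and none at least 2-fold lower, with a list median of 1.75. Formative and primed epiblast genes ran the other way: the kinase gene Pim2, at 180 FPKM in double-negative cells, differed by -3.11 and Sox3 by -2.17, the POU factor gene Pou3f1 was at 5.30 against 52.0 FPKM and Car4, a carbonic anhydrase gene, at 2.04 against 17.1. Of 14 such genes 9 were lower and none higher, with a median of -1.16. Factors shared by naive and primed cells differed little, as Pou5f1 was at 2196 against 1987 FPKM and none of 12 members reached 2-fold.

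Over all rows, 247 were at least 2-fold higher and 195 at least 2-fold lower in single-positive cells. Among the 10 protein-coding or long noncoding genes with the largest positive difference were Mylpf (2.89), Gm7325 (2.79), Serpinb6c (2.78), Khdc3 (2.78), Lrrc34 (2.76), Gjb5 (2.73), Tfap2c (2.67), Adap1 (2.58) and Mras (2.51). Gjb5, which encodes a gap junction protein, was at 17.5 against 1.79 FPKM, and the transcription factor gene Tfap2c at 48.8 against 6.84. After Pim2 (-3.11) and Pou3f1 (-3.07), the most negative included the guanylate-binding protein gene Gbp5 (-2.86), Car4 (-2.57), the WNT ligand gene Wnt8a (-2.49), Gbp2 (-2.48), Enpp2 (-2.44), Wt1 (-2.38) and Vrtn (-2.27). LIF/STAT3 response genes had a median of 0.53, with Tfcp2l1 and Klf4, both also on the naive list, as the 2 members past 2-fold among 11. NODAL/activin response genes had a median of -0.47, with 2 of 9 members lower, among them Lefty1, at 129 against 273 FPKM.

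Imprinted genes were lower in 6 of 15 measured members, with a median of -0.67. Peg10 was at 25.8 against 98.5 FPKM, the growth inhibitor gene Cdkn1c at 19.3 against 72.5, Grb10 at 17.9 against 43.4 and Dlk1 at 0.359 against 2.08. The de novo methyltransferase genes Dnmt3a and Dnmt3b were at 19.8 and 66.9 FPKM against 42.1 and 158, and they were the 2 lower members among 12 DNA methylation genes, whose median was 0.16. Lineage lists were mixed. Of 8 trophectoderm genes, Tfap2c and Tead4 were higher and Krt18 and Krt8 lower, with a median of -0.41, below the random range. Of 7 neuroectoderm genes, Tubb3 was higher and Sox11 and Nes lower. Of 9 primitive endoderm genes, Lama1 was higher and Dab2 lower, with a median of -0.43, also below it. The median ratio of single-positive to double-negative level was 0.679 over the trophectoderm and 0.721 over the primitive endoderm genes, within the range of the profile described with the Tbx3 step. Over the imprinted, NODAL response and stress genes it was 0.597, 0.719 and 0.791, also within that range. It was 0.444 over the formative, 0.882 over the FGF/ERK response and 0.931 over the p53 response genes, outside it. A ratio within that range does not by itself place a list in the profile, which also asks for low double-positive levels. Of the imprinted genes 1 is a profile row, and of the NODAL response and stress genes none. The median NODAL response level was 68.0 FPKM in double-negative, 42.3 in single-positive and 46.0 in double-positive cells. Fgf8 was the only lower one of 5 streak and mesoderm genes. The 9 WNT response genes held 1 past 2-fold, Notum, at 43.8 against 9.34 FPKM. No member reached 2-fold among 12 FGF/ERK response, 9 BMP response, 17 mitotic or 18 replication genes. Among 14 germline genes Rhox9 was higher (13.1 against 1.75 FPKM) and Mael lower (4.69 against 13.4).

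The stress list of immediate early and heat shock genes had a median of -0.34, with Atf3 lower among 13, and the p53 response list a median of -0.10, with Pmaip1 lower among 15. The fibroblast list had a median of -0.49, and 9 of its 13 measured members belong to a set of 484 rows described with the Tbx3 step. Against 10000 random lists matched on expression, 3 of the 23 fixed lists lay above the middle 95% (naive, STAT3 response and neuroectoderm) and 9 below, where chance gives 0.58 on each side. Without the wider form of that set, 9 lists in place of 12 lay outside. The counts were 581 higher and 804 lower with a pseudocount of 0.1 and no filter on low values.

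**Figure D1:**
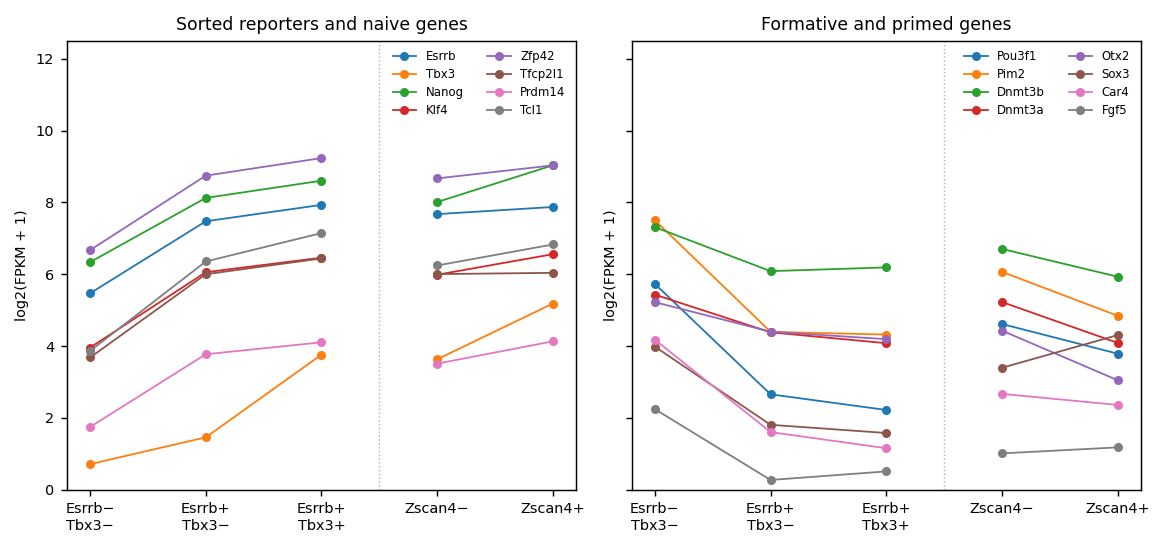
Levels of sorted reporters and naive genes (left) and of formative and primed genes (right), as log2(FPKM + 1) on the y axis against the 5 sorted fractions on the x axis. Points are the authors' single merged value per fraction, without error bars, and lines join fractions of 1 reporter line: Nanog lies at 79.8 FPKM in double-negative and 278 in single-positive cells, Pou3f1 at 52.0 and 5.30.

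The Tbx3 step compared double-positive with single-positive cells, which asks what accompanies Tbx3 once Esrrb is on. Esrrb itself was higher by 0.46, at 243 against 177 FPKM, so the step does not separate Tbx3 from the level of Esrrb. Few genes were higher: besides Tbx3 itself (2.30), the receptor tyrosine kinase gene Fgfr4 was at 20.6 against 0.837 FPKM, the noncoding RNA gene Dancr at 255 against 23.1, 2210011C24Rik at 36.3 against 2.97 and the purinergic receptor gene P2rx7 at 29.5 against 4.36. The other top genes were Calcoco2 (1.60), Commd4 (1.45), Arl14epl (1.38), the aquaporin gene Aqp3 (1.31) and Pigyl (1.25). Dancr, Commd4 and Pigyl had their lowest level in single-positive cells, and in double-negative cells, where Tbx3 is low too, they were at 93.5, 168 and 53.4 FPKM. No naive factor reached 2-fold among 16, yet the list median was 0.46, above every matched random list, and Tcl1 was at 141 against 80.8 FPKM. Because FPKM is scaled to all mapped fragments, the profile transcripts described below can lower all other values in single-positive cells. The naive median was 0.38 under equal FPKM totals and 0.42 under median-ratio scaling, and the size of this effect was not tested. Formative genes had a median of -0.18, with Lef1 (-1.07) the only one of 14 past 2-fold.

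Far more rows were lower: 943, against 47 higher. The 10 largest negative differences among coding and noncoding genes were those of the extracellular matrix genes Col1a1 (-5.57), Col1a2 (-5.51), Bgn (-5.32), Col6a1 (-5.28), Col6a2 (-5.15) and Col3a1 (-5.14), of S100a4 (-5.30), of the T-cell genes Gzma (-5.33) and Cd3g (-5.05), and of the imprinted noncoding RNA gene H19 (-5.03). Col1a1 was at 477 FPKM in double-negative and 348 in single-positive cells, but at 6.32 in double-positive, 5.61 in Zscan4-negative and 7.00 in Zscan4-positive cells. Cd3g, a T-cell receptor complex gene, was at 153, 110 and 2.35 FPKM in the first 3 of these and at 2.28 FPKM in Zscan4-positive cells. Fibroblast genes were lower in 11 of 13 members, with a median of -3.29, and T-lineage genes, listed after their values were seen, in 12 of 13, with a median of -3.31.

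This shared profile was measured as 484 rows at no more than 0.1 of the double-negative level in double-positive and both Zscan4 fractions, and at 0.5 to 1 of it in single-positive cells. Their median ratio of single-positive to double-negative was 0.701, and the middle 95% ran from 0.565 to 0.865. Of the 943 lower rows, 419 belong to it, 653 with 0.25 in place of 0.1, and 72.4% had a ratio between 0.6 and 0.8, against 12.2% of all other rows. Without the 653, which are low in double-positive cells by definition, 290 lower rows were left. This is not a count of rows free of the profile. After the double-positive level was subtracted from both columns, 45.9% of the 290 had a ratio within 0.6 to 0.8. Their median ratio was 0.640. Among rows lower in double-positive than in double-negative cells but not in the Tbx3 step, 24.1% had such a ratio. The choice of these rows limits that ratio, because their single-positive level is less than 2-fold above the double-positive level. Their share is therefore no baseline for the 290. Hprt, a purine salvage gene that E14Tg2a cells lack, was at 28.0 FPKM in double-negative, 19.3 in single-positive and 0.954 in double-positive cells.

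Other lower groups had ratios of single-positive to double-negative level inside and outside the range of the profile. Primitive endoderm genes were lower in 5 of 9 members, namely Col4a1, Col4a2, Pdgfra, Sparc and Dab2, and the basement membrane gene Col4a1 was at 0.583 against 13.5 FPKM, with 19.3 in double-negative cells. The ratio was 0.682 for Col4a2, 0.742 for Sparc, 0.669 for Pdgfra and 0.413, below the profile's range, for Dab2. The BMP response genes Id3 and Id2 were at 29.9 and 11.2 against 81.1 and 24.0 FPKM, with ratios of 0.779 and 0.580. Jun and Fos, immediate early genes, were at 2.19 and 7.64 against 13.3 and 20.1 FPKM, with ratios of 0.547 and 0.584, and were the 2 lower of 13 stress genes. Igf2, with a ratio of 0.622, and H19, at 146 FPKM in double-negative and 102 in single-positive cells, were the 2 lower of 15 imprinted genes. Tet3 (ratio 0.571) was the only lower of 12 DNA methylation genes, Snai1 (0.710) of 5 streak genes and Phlda1 (0.838) of 12 FGF/ERK response genes, while Btg2 (0.746) and Fas (0.546) were the 2 lower of 15 p53 response genes. Gata3 (0.699) and Id2 were lower among 8 trophectoderm genes, whose median of 0.25 lay above the random range. Of the genes in this paragraph so far, Pdgfra, Gata3 and H19 belong to the profile of 484 rows. Outside the wider profile the most negative genes were Cd27 (-3.20), the matrix receptor gene Ddr2 (-2.53), Nfkbiz (-2.43), Jun (-2.16), Mrc2 (-2.13), Atp6v0a2 (-1.95), Irgm1 (-1.86), Erbb2ip (-1.80), Nckipsd (-1.80) and Pde3b (-1.80). Being outside its cutoffs does not show that such genes are free of the profile. Cd27 was at 27.9 FPKM in double-negative cells, the median level of the T-lineage list there, 12.9 in single-positive and 0.510 in double-positive cells. Ddr2 was at 19.3, 12.7 and 1.36 FPKM in the same order, and Mrc2 at 15.3, 6.88 and 0.805. Nfkbiz, Atp6v0a2 and Nckipsd were instead higher in single-positive than in double-negative cells.

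Other medians in the Tbx3 step were small, and the limit of FPKM given for the naive list applies to them too. They were 0.26 for factors shared by naive and primed cells, 0.26 for STAT3 response genes, 0.24 for NODAL response genes, 0.19 for mitotic genes, 0.17 for ribosomal protein genes, 0.30 for germline genes with Rhox5 past 2-fold at 220 against 106 FPKM, and -0.04 for replication genes. The 2-cell-like list had a median of 0.30 at levels near 0, since its median member was at 0.279 FPKM in double-positive cells. Of its 25 rows Gm5662 (1.37), Gm20767 (1.09) and Gm8300 (1.07) were higher, none above 2.04 FPKM in double-positive cells, and 1 row of Sp110 (-1.98) was lower. In all, 9 lists lay above and 4 below the middle 95% of random lists. With a pseudocount of 0.1 and no filter the counts were 313 higher and 2066 lower, and with coding and noncoding symbols alone 24 were higher.

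**Figure D2:**
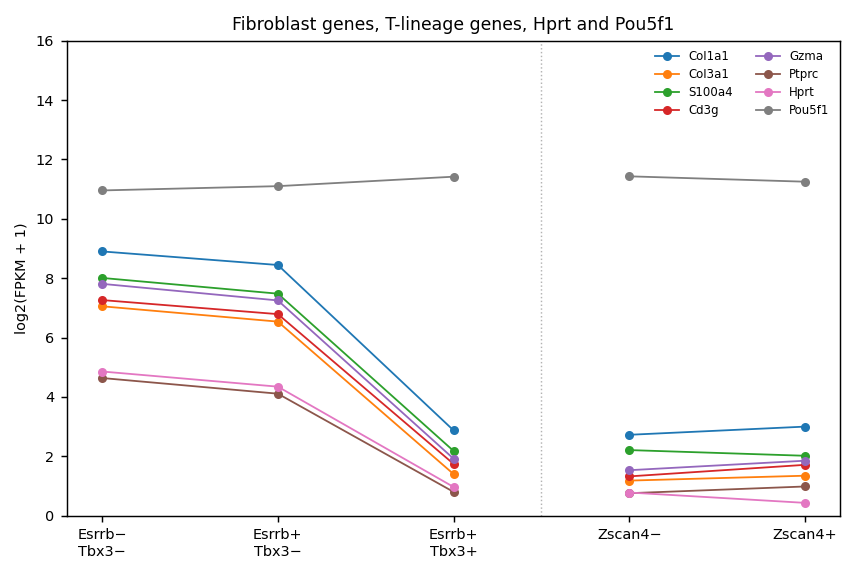
Levels of fibroblast genes (Col1a1, Col3a1, S100a4), T-lineage genes (Cd3g, Gzma, Ptprc), Hprt and the ES cell gene Pou5f1, as log2(FPKM + 1) on the y axis against the 5 sorted fractions on the x axis. Points are single merged values without error bars and lines join fractions of 1 reporter line: Col1a1 lies at 477 and 348 FPKM in the first 2 fractions and at or below 7.00 FPKM in the other 3.

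Double-positive were also compared directly with double-negative cells, the ends of the Esrrb and Tbx3 series. Naive factors were higher in 15 of 16 members, with a median of 2.17, and the exception, Gbx2, was at 23.3 against 45.5 FPKM. Tcl1 was at 141 against 13.6 FPKM, Tfcp2l1 at 85.7 against 11.8 and Zfp42 at 601 against 101. Formative genes were lower in 11 of 14, with a median of -1.54, Pou3f1 at 3.66 against 52.0 FPKM and Sall2 at 1.33 against 11.4. Mylpf (3.90), Serpinb6c (3.67), Adap1 (3.67) and Fgfr4 (3.52) were among the 5 largest positive differences. The most negative were Col1a1 (-6.03), Col1a2 (-6.01), Gzma (-5.89), Bgn (-5.87) and S100a4 (-5.83), all of the shared profile, and outside its wider form Cd27 (-4.26), Gbp2 (-3.99), Gbp5 (-3.63), Smim6 (-3.59) and Pou3f1 (-3.51). Cd27 is the gene at the median level of the T-lineage list, as given with the Tbx3 step.

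In total 518 rows were higher and 1656 lower, of which 776 belong to the wider profile, so that 880 lower rows were left without them. All 13 fibroblast genes and 6 of 15 imprinted genes were lower, and in the STAT3 response list, with a median of 0.92, 4 of 11 members were higher, namely Tfcp2l1, Klf4 and Klf5, which are on the naive list too, and Icam1, and Gadd45g was lower (-1.49). Medians were -0.36 for FGF/ERK response genes, -0.58 for stress genes, with Jun, Fos, Fosb and Atf3 lower, and 0.43 for mitotic genes. The limit of FPKM given with the Tbx3 step applies here too, through the profile transcripts in double-negative cells. Under equal FPKM totals the mitotic median was 0.31 and the FGF/ERK median -0.47. WNT response genes had a median of 0.10, with Notum higher and Lef1 and Tcf7 lower. For the 518 higher rows the Esrrb step held a median of 70.6% of the whole log2 difference, and 86.9% of them had more than 50% of it there. For the 1656 lower rows that median was 25.8%, and 38.1% without the wider profile, whose rows have a small share in the Esrrb step by definition. The 7 lists above and 7 below the middle 95% of random lists kept the sign of their medians under both other scalings of the columns.

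The Zscan4 sort compared Zscan4-positive with Zscan4-negative cells, which asks what else is transcribed in the state the promoter marks. All 25 measured rows of the list of 2-cell-embryo-like genes, which leaves out the Zscan4 family, were at least 2-fold higher, with a median of 4.41. These rows stand for 23 of the 29 listed genes. Many passed the 1 FPKM filter only through Zscan4-positive cells, so the count is partly set by that filter. The list's median level was 20.5 FPKM in Zscan4-positive cells and no more than 0.279 in any other fraction. Gm5662 was at 191 against 0.216 FPKM, Gm20767 at 149 against 0.310, Gm8300 at 126 against 0.133, Tmem92 at 47.5 against 0.0690 and the homeobox gene Dux, an activator of 2-cell transcripts, at 7.99 against 0.0338. With Zscan4d, Zscan4c and Zscan4f, the other top genes were Gm12794 (6.44), Gm2022 (6.29) and Gm2016 (6.06). Many of these genes belong to multicopy families whose copies share reads, such as the 5 Usp17-like genes, at 10.6 to 50.6 FPKM in positive cells. Pou5f1 was at 2437 against 2762 FPKM in Zscan4-positive cells and Utf1, also shared by naive and primed cells, at 266 against 501, while Dppa2, Nanog and Fbxo15 were higher, at 124 against 48.6, 522 against 257 and 921 against 162 FPKM.

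In total 470 rows were higher and 119 lower. Of 16 naive factors, Fbxo15, Jam2 and Nanog were higher and Gbx2 lower (-1.49), with a list median of 0.35. Formative genes were lower in 6 of 14, with a median of -0.80: Otx2 was at 7.27 against 20.5 FPKM, Pim2 at 27.7 against 66.0, and Sall2 at 1.94 against 5.79, and Dnmt3a differed by -1.14. Germline genes had a median of 0.54, and Tex19.1 (71.4 against 23.7 FPKM), Dazl (13.2 against 4.07) and Taf7l (4.31 against 1.01) were the 3 of 14 past 2-fold. p53 response genes had a median of 0.39, with the apoptosis gene Pmaip1 at 32.9 FPKM (1.76) and Plk2 at 36.1 against 15.4. Imprinted genes had a median of -0.33, and the 3 lower members of 15, Mirg, Meg3 and Rian, are noncoding RNA genes of 1 imprinted cluster. Primitive endoderm genes had a median of 0.34 with none of 9 past 2-fold, mitotic genes a median of 0.18 with none of 17, and streak genes a median of 0.68 with Snai1 and Gsc higher among 5.

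The most negative coding and noncoding genes included the phosphatase gene Ctdsp2 (69.8 against 343 FPKM), the interferon-inducible genes Gbp2 (1.09 against 7.15) and Zbp1 (0.889 against 5.40), Hes6 (-1.73), Cnpy1 (-1.64), Prtg (-1.57), Tagln (-1.54), Mirg (-1.53) and Meg3 (-1.51). Medians of the other fixed lists lay within the random range, among them -0.13 for factors shared by naive and primed cells, 0.21 for BMP response genes with Id3 higher, -0.15 for DNA methylation genes with Dnmt3a lower, 0.12 for fibroblast genes, -0.01 for glycolysis genes with Pdk1 lower, 0.04 for ribosomal protein genes and -0.01 for stress genes. The replication, NODAL response and ribosomal protein lists sat at the edge of that range, with percentiles of 2.59, 2.97 and 97.48. The ribosomal list lay outside it under median-ratio scaling and had a negative median (-0.01) under equal FPKM totals. The counts were 1527 higher and 418 lower with a pseudocount of 0.1 and no filter, and 144 were higher where at least 5 FPKM in at least 2 fractions was required.

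**Figure D3:**
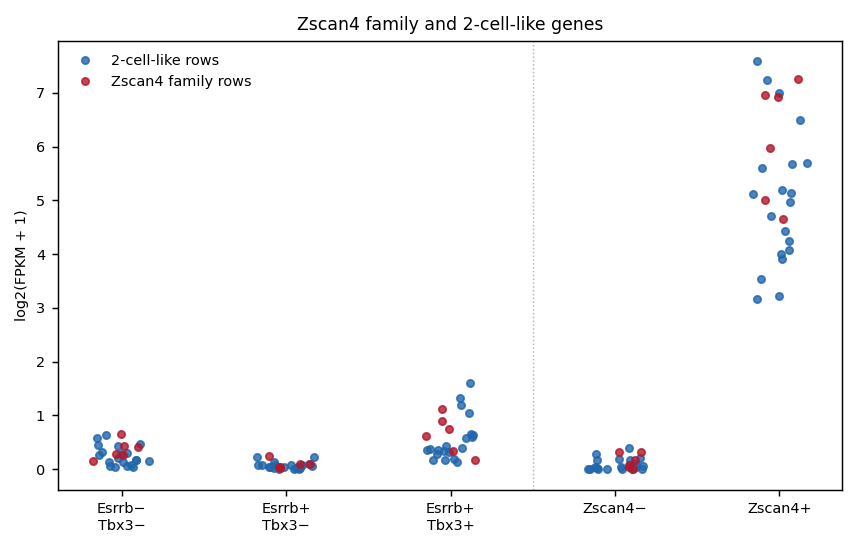
Levels of the 26 rows of the Zscan4 family (red) and of the 2-cell-like list (blue) with at least 5 FPKM in Zscan4-positive cells, as log2(FPKM + 1) on the y axis against the 5 sorted fractions on the x axis, with points spread sideways for visibility. Each point is 1 row's single merged value without error bars: Zscan4c lies at 120 FPKM in Zscan4-positive and 0.255 in Zscan4-negative cells.

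The sorts were then set side by side. The 195 rows lower in the Esrrb step and the 119 lower in the Zscan4 sort shared 46 rows, where independent lists of that size would share 1.71. Among the 46 were Pim2, Wnt8a, Enpp2, Wt1, Vrtn, Gbp2, Gbp5 and Dnmt3a. The 247 rows higher in the Esrrb step and the 470 higher in the Zscan4 sort shared 23, against 8.54 for independent lists, among them Nanog, Fbxo15, Jam2, Aqp3 and Mreg, the last at 478 FPKM in Zscan4-positive and 17.5 FPKM in double-negative cells. Opposite directions also exceeded independent lists: 7 rows were higher in the Esrrb step and lower in the Zscan4 sort, against 2.16, and 13 the reverse, against 6.74. With the Zscan4 sort, the Tbx3 step shared 18 rows higher in both, against 1.62, and 18 lower in both, against 8.25. A further 8 rows were higher in the Tbx3 step and lower in the Zscan4 sort, against 0.411, and 27 the reverse, against 32.6. Short RNAs, unmatched rows and the wider profile carried part of these. Without them the Esrrb step and the Zscan4 sort shared 41 lower rows, against 1.11, and 21 higher, against 7.12, while the opposite directions held 2, against 1.46, and 7, against 5.39. The Tbx3 step then shared 11 higher rows with the Zscan4 sort, against 0.780, and 9 lower, against 1.71, and the opposite directions held 2, against 0.160, and 21, against 8.35. Across rows, which are not independent, the double-positive and the Zscan4 differences had r = 0.0960, the Esrrb step and the Zscan4 sort r = 0.0828, and the Tbx3 step and the Zscan4 sort r = 0.0716. The Esrrb and Tbx3 steps had r = 0.245 and a Spearman rho of 0.563. The r was -0.504 in simulated fractions without any difference, because both use the single-positive values with opposite signs, and 0.425 over coding and noncoding symbols alone. The steps differed by at least 2-fold from each other in 980 rows, and the Zscan4 and double-positive differences in 2510.

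**Figure D4:**
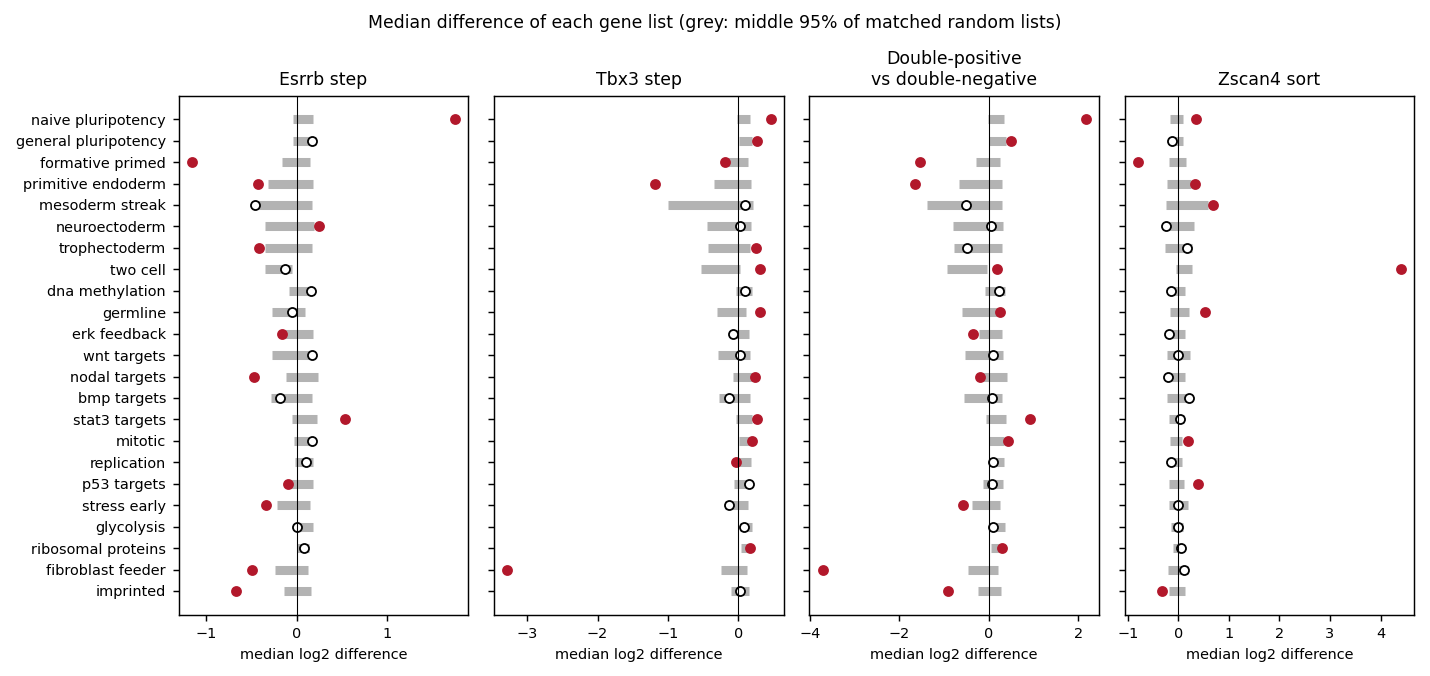
Median log2 difference (x axis) of each of the 23 fixed gene lists (y axis) in the 4 comparisons (panels). Grey bars span the middle 95% of 10000 random lists matched on expression, and filled red points lie outside them: the 2-cell-like list is at 4.41 in the Zscan4 sort, and the fibroblast list at -3.29 in the Tbx3 step.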

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

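No paired analysis was possible because the 2 libraries of each fraction are merged into 1 value. For the same reason the planned other normalizations, count filters, tests, thresholds, sample subsets, list tests and single-library omissions were not run. Of the alternatives below, the pseudocount of 0.1 without a filter and the summed Zscan4 family were planned, and all others were chosen after seeing the data. Summing the Zscan4 family gave 465 higher rows in the Zscan4 sort against 470. None of the 259 single-gene differences changed sign under any alternative run, and 108 moved by over 1.5-fold with a pseudocount of 0.1, which weighs low values more.

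With a pseudocount of 0.1 and no filter, more rows entered and the higher and lower counts were 581 and 804 in the Esrrb step, 313 and 2066 in the Tbx3 step, 1033 and 3267 for double-positive against double-negative cells, and 1527 and 418 in the Zscan4 sort. The steps then differed in 3235 rows and the 2 sorts in 5387, and r between the steps was 0.120. With a pseudocount of 0.1 and the filter kept, they were 428 and 469 in the Esrrb step, 153 and 1460 in the Tbx3 step, and 835 and 280 in the Zscan4 sort, with 1871 rows differing between the steps. Where at least 5 FPKM in at least 2 fractions was required, fewer rows entered: 95 were lower in the Esrrb step, 475 in the Tbx3 step and 753 in double-positive cells, 144 were higher in the Zscan4 sort, and 560 and 1173 differed between the steps and between the sorts. With coding and noncoding symbols alone, 24 rows were higher in the Tbx3 step and r between the steps was 0.425. The rows left out include short RNAs with large opposite differences in the steps, such as Mir3968 (10.7 and -10.7), which lower r over all rows. How much of the change such rows account for was not tested.

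Other correlations stayed within 0.1 of their values, but those with the Zscan4 sort are small: r of the Esrrb step with it, 0.0828, was 0.0138 to 0.0153 with a pseudocount of 0.1 and 0.160 with the 5 FPKM filter. Across the alternatives 9 to 13 lists lay outside the random range in the Esrrb step, 11 to 14 in the Tbx3 step, 12 to 16 in the double-positive comparison and 9 to 11 in the Zscan4 sort.

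Without the shared profile at 0.1, 524 rows were lower in the Tbx3 step, the steps differed in 629, and the Esrrb step held a median of 42.8% of the whole difference, against 32.0%. The profile's rows have a small share in the Esrrb step by definition, so leaving them out raises it. At 0.25 these values were 290, 484 and 51.3%, and 880 rows were lower in double-positive cells. Scaling to equal totals or by median ratios, and summing rows of 1 symbol, left all 19 summary results within their tolerance. Equal totals moved the median of all rows by -0.11 in the double-positive comparison, and the double-positive counts became 427 higher and 1855 lower. Depth per library is unknown, so no limit of detection can be given.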

Other observations

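All tests in this part were chosen after the results were seen. Interferon response genes, a list made after some values were seen, were lower along both sorts. In the Esrrb step 7 of 13 members were at least 2-fold lower, with a median of -1.23: Gbp2 was at 4.39 against 29.1 FPKM, Oasl2 at 1.35 against 9.62, Zbp1 at 4.61 against 23.0 and Irf1 at 35.4 against 84.2. In the Zscan4 sort 6 of 13 were lower, with a median of -0.82, and Irf1 was at 14.1 against 30.4 FPKM. All 13 were lower in double-positive than in double-negative cells, with a median of -2.85.

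The 2 reporter lines also differed in genes unrelated to the sorts. Mest, an imprinted gene, was at no more than 4.22 FPKM in the Esrrb/Tbx3 fractions and at 75.3 and 70.1 FPKM in the Zscan4 fractions. The Y-linked gene Eif2s3y was at 78.2 and 82.4 FPKM in Zscan4-negative and Zscan4-positive cells but at 0.106 FPKM in double-positive cells, and Ddx3y and Uty at 0.0750 and 0.0104 FPKM there against 12.7 and 10.1 FPKM in Zscan4-negative cells. Kdm5d, the other Y-linked gene examined, was low in both lines, at 0.0384 FPKM in Zscan4-negative and 0.104 in Zscan4-positive cells against 1.11 FPKM in double-negative cells. Its ratio of single-positive to double-negative was 0.832 and it belongs to the profile of 484 rows, while Eif2s3y, Uty and Ddx3y, with ratios of 0.652, 0.648 and 0.627, do not. In double-negative and single-positive cells Eif2s3y was at 4.24 and 2.77 FPKM. Xist, transcribed from the inactive X chromosome of female cells, was at 11.2 and 7.43 FPKM in these 2 fractions and at 0.408 in double-positive, 0.380 in Zscan4-negative and 0.603 in Zscan4-positive cells.

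The first pattern weighed is the fibroblast and T-lineage profile of the double-negative and single-positive columns. The profile is not limited to genes of these lineages. It also holds the ribosomal protein gene Rpl29, at 64.1 and 44.6 FPKM in these columns and no more than 1.66 in the other 3. The ferritin gene Ftl1, at 229 and 169 FPKM against no more than 9.39, is another. Why such genes share the profile was not tested. Feeder fibroblasts or differentiation towards fibroblasts alone would leave the T-lineage genes, with a median of 27.9 FPKM in double-negative cells, unexplained. That list was made after its values were seen, so its median restates the pattern and is not a separate test of this explanation. The ratio between the columns differed by -0.0098 (log2) between the fibroblast and T-lineage lists. In each list 9 of 13 measured members are profile rows, and the profile's rule limits that ratio. The small difference is therefore only weak evidence against separate fibroblast and T-lineage sources mixed independently. A candidate source is RNA or reads from outside the ES line, since Hprt, which E14Tg2a cells lack, was at least 20.3 times higher in both columns than in the other 3, and the Y-linked genes, nearly silent in the double-positive column, had a median ratio of 0.650 with Kdm5d included, within the profile's range. Xist beside Y-linked genes would need male and female cells in such a source, and a gate on Esrrb fluorescence would remove non-fluorescent foreign cells from the single-positive fraction, which speaks against mixing of such cells before the sort and leaves mixing of RNA or reads after it open, though neither was tested. The biological difference between the sorted states was not tested apart from such a source.

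The second pattern is the trace of 2-cell-like transcripts outside Zscan4-positive cells, at a median of 1.02% of their Zscan4-positive level in double-positive, 0.400% in double-negative, 0.104% in single-positive and 0.107% in Zscan4-negative cells. Carry-over of reads at 1 rate into every column is argued against by these shares, whose highest was 9.75 times the lowest. Across the 26 rows the double-positive levels followed the Zscan4-positive ones, with a Spearman rho of 0.889, as a small share of such cells or of their reads in that column would give. The rho of 0.895 in the double-negative column was alike, so the test does not single out double-positive cells, and a biological overlap of the states remains open.

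The third pattern is the lower level of interferon genes in single-positive and Zscan4-positive cells. In the Zscan4 sort the interferon list had a median of -0.82. The 80 profile rows of at least 20 FPKM were at a median of 2.01% of their double-negative level in Zscan4-negative cells. In Zscan4-positive cells they were at 2.59%. The list was made after some values were seen, and the profile's rule keeps its rows low in both Zscan4 fractions. The values of the profile rows therefore cannot decide whether foreign RNA is the whole cause. The fibroblast list, fixed before the data were examined, had a median of 0.12 in the Zscan4 sort. Its median ratio of single-positive to double-negative was 0.697. That of the interferon list was 0.421, below the profile's range of 0.565 to 0.865. For the listed genes as a set, these medians argue against foreign RNA of the profile as the whole cause, without a replicate check. Psmb8, 1 of the 13 members, does belong to the profile, so part of the difference in the Esrrb and Tbx3 series may come from the profile. The list does not cover every interferon-inducible gene, and Tap2, Igtp, Ifi27 and Iigp1 are profile rows too. The share of listed members therefore does not measure how far the interferon genes and the profile overlap. A link to the sorted states themselves remains a hypothesis that was not tested.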
